A study of Caenorhabditis elegans with 9 samples.

How the data were processed

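Total RNA of whole young adult animals was labelled with biotin by 3' in vitro transcription and hybridised to the Affymetrix C. elegans Genome Array, 1 sample per array, per the labels. The deposited values are log2 expression levels per probe set that the authors made with RMA, and limma was used by them as well, per the submitters' processing notes. The versions of these tools, and whether arrays were weighted or blocked, are not given in the sources used here. RMA subtracts a background per array, equalises the distributions of the arrays and sums probes into probe sets, so a shift that moved most genes alike would be removed, and low levels are compressed.

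The array holds 22625 probe sets. The 77 control probe sets were left out of the tests and read separately for RNA integrity, hybridisation and labelling, leaving 22548. In the probe annotation given, 20766 of these name 1 gene, 887 name several and 895 name none, and the first kind covers 17118 genes, of whose probe sets 20701 matched the reference gene table (assembly WBcel235) and 65 did not. Probe sets that can detect several related genes, 6711 by their names, were kept, with an alternative without them. This matters for gene families with near-identical members, such as the major sperm proteins, histones and vitellogenins.

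Groups were taken from the sample titles and genotypes. All 9 arrays entered 1 limma fit (limma 3.58.1 with statmod 1.5.0 in R 4.3.3) with a mean per group, 6 residual degrees of freedom and 2.38 prior degrees of freedom. Contrasts were each mutant strain against wild type, the unweighted mean of both against wild type, and n4503 nDf57 against n4357 n4358. P-values were adjusted by Benjamini-Hochberg over all probe sets with a threshold of 0.05. Single genes named in advance were also tested by two-sided exact permutation of 6 arrays against 3. Tables and figures were made with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. The fit was tested on simulated data with 200 changed probe sets in 5 runs per size of change, with noise drawn independently for each probe set.

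Gene lists were written from general knowledge before the data were examined, as were the comparisons, the tests, the rule for named genes and the alternatives, except the 4 alternatives given below as added. Exact permutation was planned for the RNA integrity controls only. Its use on single genes and on list means was not part of that plan. They were piRNA pathway factors, Argonautes, RNA interference machinery, P granule proteins, meiotic chromosome proteins, major sperm proteins, other sperm genes, oocyte and eggshell genes, vitellogenins, zygotic embryo genes, markers of intestine, muscle and neurons, male-specific neuron and gland genes, cuticle collagens, moulting genes, heat shock genes, endoplasmic reticulum stress genes, detoxification enzymes, innate immune effectors, intracellular pathogen response genes, DAF-16 targets, ribosomal proteins, oxidative phosphorylation genes, proteasome subunits, histones, DNA replication and cell division genes, F-box and MATH-domain families, chemoreceptor families and transposon genes. Each gene was represented by the probe set with the highest mean over all arrays. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over 29 lists. Unless said otherwise a list's adjusted p is that of camera with the preset correlation. Camera compares a list with all other genes, so its direction can differ from the sign of a median near 0.

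The rule for named genes took prg-1, prg-2, bath-45 and xol-1 in every case, then probe sets past the threshold with fully separated groups, of which there were 0, and in each list without a called member the member with the smallest adjusted p. Adjusted p-values of list members were tied at 0.999 in the main comparison, apart from bath-45, and ties were broken by the unadjusted p. In the comparisons of single strains this was done for the lists that passed camera. Other genes are said to have been chosen after their values were seen, or lie next to prg-1 or prg-2 in the reference.

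The alternatives were a replicate block, a filter on probe sets below the 30th percentile of mean level, a variance trend with robust estimation, array weights, only the arrays compared, cyclic loess, centring on ribosomal and proteasome genes, the mean of all probe sets per gene, thresholds of 0.01 or of a 2-fold change, no shared probe sets, an estimated correlation, and leaving out each array in turn. Added after seeing the data were 3 covariates, namely the first component of variation inside the groups, the mean of the moulting genes and the mean of the hybridisation controls, and a fit of the 6 arrays on one side of that component. A test of called genes by chromosome could not be run because no gene was called. Probe sequences and their positions were not used here.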

Results

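Messenger RNA was measured in whole animals of Caenorhabditis elegans, labelled as young adults, on 9 one-colour Affymetrix arrays. Of these, 3 arrays held N2, the standard wild-type strain. A further 3 held strain MT14769, which carries the alleles n4357 of prg-1 and n4358 of prg-2, and 3 held strain SX9, which carries n4503 of prg-1 and nDf57 of prg-2. prg-1 encodes a Piwi-class Argonaute protein, the partner of the small germline RNAs called piRNAs, and prg-2 is its close relative, which the reference lists as a pseudogene. The design asks how messenger RNA levels differ in animals mutant for both genes, and sets independent alleles side by side. Values are RMA expression levels on the log2 scale, with array medians between 4.76 and 4.83 log2. The number of arrays, 3 per group, limits the precision of each value. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, part of which may be technical. The list mean of the moulting genes, for example, ran from -0.30 to 0.27 log2 in wild type, -0.67 to 0.40 in n4357 n4358 and -0.65 to 0.31 in n4503 nDf57. These ranges alone do not tell a technical from a biological spread.

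The mutated genes were examined first. The prg-1 probe set gave a level of 6.16 ± 0.76 log2 in wild type (SD, n = 3), 6.72 ± 1.24 in n4357 n4358 (SD, n = 3) and 7.10 ± 0.39 in n4503 nDf57 (SD, n = 3). On single arrays prg-1 stood at 6.93, 6.13 and 5.41 in wild type, at 6.74, 7.95 and 5.47 in n4357 n4358, and at 7.50, 6.72 and 7.07 in n4503 nDf57. The mean of both mutants lay 0.75 log2 above wild type for prg-1 (SE 0.53; exact permutation test, two-sided p = 0.262). Without replicate 2 of n4357 n4358, that strain's prg-1 difference from wild type turned from 0.56 to -0.05. With single arrays left out the mean prg-1 difference ran from 0.37 (without wild-type replicate 3) to 1.14 (without wild-type replicate 1), and that of n4503 nDf57 from 0.56 to 1.33 without the same arrays. The prg-2 probe set gave 6.29 ± 0.27 log2 in wild type, 5.87 ± 0.35 in n4357 n4358 and 6.03 ± 0.21 in n4503 nDf57 (SD, n = 3 each), a mean difference of -0.35 (SE 0.18; exact permutation p = 0.131). This prg-2 difference ran from -0.49 without wild-type replicate 3 to -0.23 without wild-type replicate 1. The prg-1 probe set is of a kind that can detect several related genes, so its signal may not be that of prg-1 alone. Where these probes lie relative to the mutated parts of the genes is not given in the sources used here, so their levels check no label.

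The mean of both mutants against wild type was the main comparison. The gene with the smallest p was bath-45, a member of the BTB and MATH-domain family and a known target of piRNAs. It stood at 4.50 ± 0.12 log2 in wild type (SD, n = 3), 5.75 ± 0.31 in n4357 n4358 (SD, n = 3) and 6.25 ± 0.14 in n4503 nDf57 (SD, n = 3). The lowest of the 6 mutant arrays, at 5.43, lay above the highest wild-type array, at 4.62. The mean difference for bath-45 was 1.5 log2 (SE 0.14), a 2.82-fold higher level. Its exact two-sided permutation p was 0.0119, the smallest that the 84 splits of 6 arrays against 3 allow. This permutation p became 0.0476 after Benjamini-Hochberg adjustment over the 4 genes named in advance. The genes were fixed beforehand, but this permutation test and its adjustment were not. The sources used here do not say whether bath-45 was known as a target independently of these arrays. If it was not, adjustment over 4 genes is too lenient. Over all 22548 probe sets the limma adjusted p of bath-45 was 0.0907, above the threshold of 0.05. Adjusted over the list alone, the 395 measured F-box and MATH-domain genes, it was 0.00159. Over all probe sets it fell below the threshold with array weights and under cyclic loess, at 0.00147 and 0.0343 within a range of 0.00147 to 1 over 21 alternatives. Another known piRNA target, xol-1, the master switch of sex determination, stayed near the lower end of the scale at 2.92 ± 0.06 log2 in wild type, 2.92 ± 0.13 in n4357 n4358 and 2.97 ± 0.10 in n4503 nDf57 (SD, n = 3 each), a mean difference of 0.03 (exact permutation p = 0.679).

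**Figure D1:**
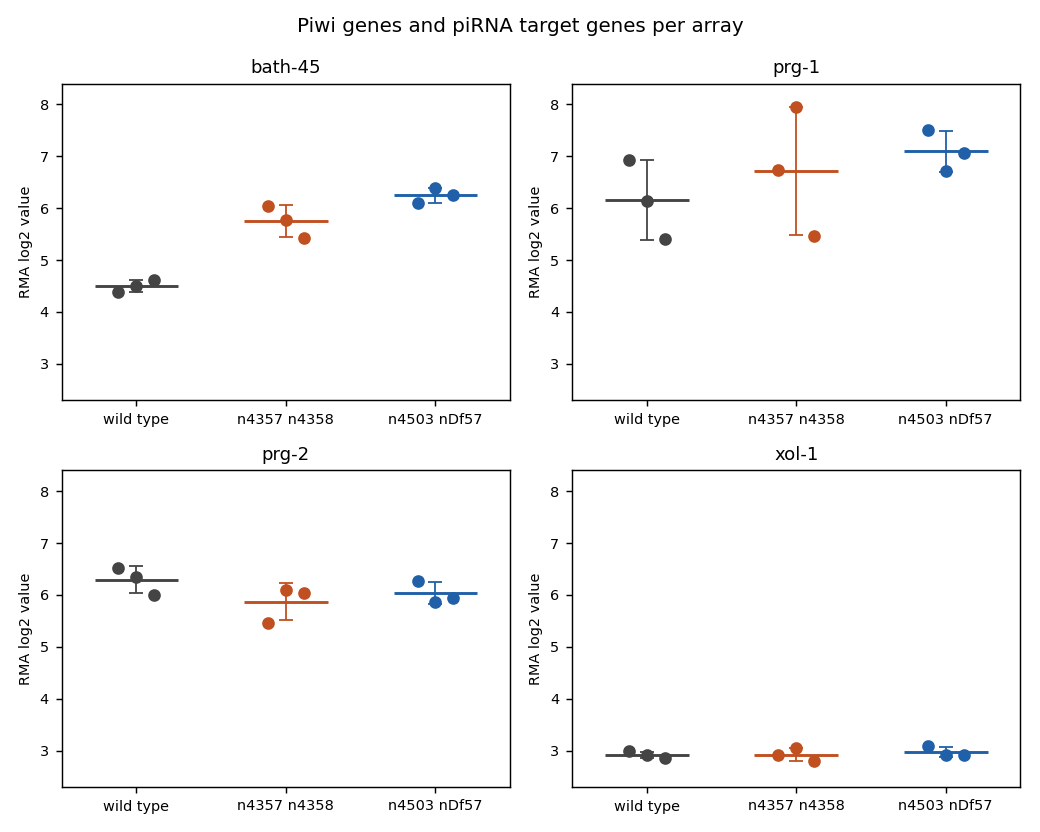
Array values of prg-1, prg-2, bath-45 and xol-1, as RMA log2 values, in the 3 groups; points are single arrays, horizontal lines group means and error bars SD (n = 3). For bath-45 all 6 mutant arrays, from 5.43 upward, lie above the 3 wild-type arrays, which reach 4.62.

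With limma and Benjamini-Hochberg adjustment, 0 probe sets were higher and 0 lower in the mean of both mutants at the threshold of 0.05. At an unadjusted p under 0.05 there were 815 probe sets, 425 higher and 390 lower, against 1127.4 expected by chance. With array weights 2 passed, both higher. These weights leaned on single arrays, at 6.64 for n4503 nDf57 replicate 2 and 3.35 for n4357 n4358 replicate 2. In n4503 nDf57 replicates 1 and 3 had 0.298 and 0.834, and in n4357 n4358 they had 0.856 and 0.148. In 237 probe sets all 6 mutant arrays lay above all wild-type arrays and in 181 all lay below, where chance gives 268.4 each way. On simulated data with 200 of the 22548 probe sets changed, the same comparison recovered 67% of changes of 1 log2 and 93.9% of changes of 2 log2. The simulated noise was drawn for each probe set alone, without the variation that many genes share across the real arrays. These percentages therefore do not say how many such changes the real arrays would reveal. The 0 calls do not show that changes are absent.

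Among genes of small RNA pathways, parn-1, the nuclease that trims the 3' ends of piRNA precursors, had a level of 5.27 ± 0.16 log2 in wild type, 5.85 ± 0.14 in n4357 n4358 and 5.73 ± 0.19 in n4503 nDf57 (SD, n = 3 each), with all 6 mutant arrays above wild type. Its difference of 0.52 (SE 0.12) had a limma adjusted p of 0.0254 adjusted over the list alone, the 11 piRNA pathway factors, and of 0.999 over all probe sets. The first of these became 0.0623 with the replicate number as a block, 0.152 with the hybridisation controls as a covariate and 0.128 with only 6 arrays. It ran up to 0.149 when single arrays were left out, passing the threshold no more without wild-type replicate 2 or 3, n4357 n4358 replicate 1 or 2, or n4503 nDf57 replicate 1 or 2. The difference itself stayed between 0.42 and 0.58 over 22 alternatives. The piRNA factors as a list had 5 positive and 6 negative differences, a median of -0.03 and a mean of 0.10, and camera's test pointed upward with an adjusted p of 0.481. The 21 Argonautes had a median of 0.09 (adjusted p = 0.101 by camera), with sago-1, an Argonaute of secondary small RNAs, at 0.33 (SE 0.10). The 25 genes of the RNA interference machinery had a median of -0.04 (camera adjusted p = 0.704), with rde-10 at 0.28 (SE 0.12). Proteins of P granules, the germline bodies in which Piwi resides, had positive differences in 12 of 14 members and a median of 0.14 (camera adjusted p = 0.0215). That call was lost with an estimated correlation between genes (adjusted p = 0.739) and was kept in 4 of 9 fits without single arrays. An exact permutation test of the list mean gave p = 0.131. The member with the smallest p, glh-4, a germline helicase, stood 0.28 higher (SE 0.09; 0.201 adjusted over the list alone).

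Among germline and reproductive genes, the major sperm proteins and vitellogenins had the largest median differences of all lists. All 23 major sperm protein genes, which encode the motility and signalling protein of sperm, were lower, with a median of -1.33 (camera adjusted p = 4.27e-14; adjusted p = 0.739 with an estimated correlation). Their mean relative to all 9 arrays was 0.81, 1.42 and 0.33 log2 in wild type, 0.49, -2.15 and 1.05 in n4357 n4358, and 0.37, -0.89 and -1.44 in n4503 nDf57. An exact permutation test of these list means gave p = 0.167. Only 1 of the 23 genes had a probe set not of the kind that can detect several related genes, and its difference was -0.23. Agreement among the 23 may therefore overstate how many genes differed. One member, msp-19, stood at 10.22 ± 0.63 log2 in wild type, 9.31 ± 1.30 in n4357 n4358 and 8.66 ± 0.94 in n4503 nDf57 (SD, n = 3 each). Other sperm genes, 57 in number, had a median of -0.08 (camera adjusted p = 0.00166; adjusted p = 0.978 with an estimated correlation), with spe-10, needed for sperm formation, at -0.28 (SE 0.10). All 5 vitellogenins, the yolk proteins of the adult intestine, were lower, with a median of -0.48 (camera adjusted p = 0.0018; adjusted p = 0.739 with an estimated correlation). Of these, vit-4 stood at 6.61 ± 1.53 log2 in wild type, 4.97 ± 0.66 in n4357 n4358 and 5.02 ± 0.90 in n4503 nDf57 (SD, n = 3 each). The major sperm protein genes and the vitellogenins also moved with the strongest source of variation inside the groups, on which wild-type replicate 2, n4357 n4358 replicate 3 and n4503 nDf57 replicate 1 lay apart. Their median loadings on it were 2.19 and 1.55. The 29 meiotic chromosome proteins had a median of 0.11 (camera adjusted p = 0.351), with syp-4, of the synaptonemal complex, at 0.31 (SE 0.11). The 34 oocyte and eggshell genes had a median of 0.05 (adjusted p = 0.704), with mex-6 at 0.25 (SE 0.10). The 51 zygotic embryo genes had a median of 0.02 (adjusted p = 0.922) that turned negative under cyclic loess, with sdz-24 at -0.49 (SE 0.23).

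Among somatic and metabolic groups, 29 of 33 oxidative phosphorylation genes were higher, with a median of 0.14 (camera adjusted p = 5.74e-06; adjusted p = 0.739 with an estimated correlation). In this group mev-1, a subunit of respiratory complex II, stood 0.36 log2 above wild type (SE 0.15). Muscle markers were higher in 29 of 32 members, with a median of 0.15 (camera adjusted p = 3e-04; adjusted p = 0.739 with an estimated correlation). The troponin gene tni-3 was at 7.17 ± 0.36 log2 in wild type, 7.97 ± 0.23 in n4357 n4358 and 7.69 ± 0.20 in n4503 nDf57 (SD, n = 3 each). Targets of the insulin-regulated transcription factor DAF-16 were higher in 11 of 13 members, with a median of 0.31 (camera adjusted p = 0.00166; adjusted p = 0.739 with an estimated correlation). The small heat shock gene sip-1, which also belongs to the heat shock list, stood at 6.78 ± 0.85 log2 in wild type, 8.15 ± 0.12 in n4357 n4358 and 8.52 ± 0.97 in n4503 nDf57 (SD, n = 3 each). Its limma p-values were 0.0684 and 0.113 adjusted over each list alone. Histone genes were higher in 21 of 26 members, with a median of 0.15 (camera adjusted p = 0.0154; adjusted p = 0.978 with an estimated correlation). Among them his-42 stood at 0.31 (SE 0.14). Ribosomal protein genes were lower in 57 of 75 members, with a median of only -0.02 (camera adjusted p = 0.00616; adjusted p = 0.978 with an estimated correlation). Among these rpl-29 stood at -0.25 (SE 0.17). DAF-16 targets and histones also moved with the variation inside the groups, with median loadings of 0.43 and 0.20. Markers of intestine (18 genes, median 0.07, adjusted p = 0.875) and of neurons (33 genes, median 0.01, mean -0.01, adjusted p = 0.940) passed no test. Nor did the male-specific genes (8 genes, median 0.06, adjusted p = 0.481). Their members with the smallest p were the protease cpr-5 at 1.13 (SE 0.50), ric-19 at -0.20 (SE 0.10) and cwp-4 at 0.15 (SE 0.10). The 147 cuticle collagens had a median of 0.03 (adjusted p = 0.704), with col-153 at -0.46 (SE 0.15). The 23 moulting genes had one of -0.09 (adjusted p = 0.206), with mlt-10 at 0.27 (SE 0.21).

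No stress or defence list passed the preset camera test in this comparison, DAF-16 targets aside. The 303 innate immune effectors had 202 positive differences and a median of 0.06 (adjusted p = 0.206). Their member irg-3, an infection response gene, stood at 10.61 ± 0.52 log2 in wild type, 9.48 ± 0.41 in n4357 n4358 and 9.12 ± 0.30 in n4503 nDf57 (SD, n = 3 each). It lay below wild type on all 6 mutant arrays, with a limma p of 0.235 adjusted over the list alone. The 14 heat shock genes (median 0.04, adjusted p = 0.704) and the 19 endoplasmic reticulum stress genes (median 0.02, adjusted p = 0.788), with sel-1 at -0.23 (SE 0.14), had medians close to 0, although sip-1 of the heat shock list stood at 1.56 (SE 0.45). The 178 detoxification enzymes had a median of 0.01, which turned negative under cyclic loess, a mean of -0.01 and a downward camera test (adjusted p = 0.674). Of these, ugt-64 stood at 0.62 (SE 0.13) and above wild type on all 6 mutant arrays. The 27 intracellular pathogen response genes (median 0.01, negative under cyclic loess, adjusted p = 0.875) held pals-32 at 0.27 (SE 0.13). The 33 proteasome subunits had a median of 0.01, a mean of -0.02 and a downward test (adjusted p = 0.481), with rpn-12 at -0.19 (SE 0.12). For the 34 DNA replication and cell division genes the median was -0.03 (adjusted p = 0.310), with cyb-2.1 at -0.27 (SE 0.15). The F-box and MATH-domain families as a whole had a median of 0.02, negative under cyclic loess (adjusted p = 0.704). The 1325 chemoreceptor genes had a median of 0.01, also negative under cyclic loess, with a downward test (adjusted p = 0.922) and str-124 at -0.39 (SE 0.12).

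Of 29 lists, 9 passed camera with the preset correlation, 5 upward and 4 downward. With camera 0 passed with an estimated correlation or with fry, limma's rotation test, where the smallest adjusted p-values were 0.739 and 0.837. Exact permutation of each list's mean over arrays gave p under 0.05 for 2 lists, the DAF-16 targets (p = 0.0238) and the oxidative phosphorylation genes (p = 0.0357), and the smallest value after Benjamini-Hochberg adjustment over the 29 lists was 0.518. Without wild-type replicate 2 the preset calls of the vitellogenins (median -0.15), muscle markers (0.05), oxidative phosphorylation genes (0.04), histones (0.06), P granule proteins and other sperm genes were lost. Histones passed in 5 and other sperm genes in 6 of the 9 fits without single arrays. Without wild-type replicate 1 that of the ribosomal proteins was lost, and their median became 0.0045. The major sperm proteins and DAF-16 targets passed in 9 of 9 such fits, though the median of the first shrank to -0.82 without n4357 n4358 replicate 2, and that of the second to 0.22 without wild-type replicate 2. Without shared probe sets 2 of the 9 lists passed, the DAF-16 targets (median 0.18, adjusted p = 0.0280) and the oxidative phosphorylation genes (median 0.11, adjusted p = 0.0120). The medians of the histones and other sperm genes then turned to -0.09 and 0.02, and the major sperm proteins had 1 member left and could not be tested. Among the genes named from the lists, the mean differences of vit-4 (-2.46 to -0.98) and cpr-5 (0.61 to 1.82) ran widest with single arrays left out. Those of col-153 (-0.63 to -0.30), mlt-10 (0.19 to 0.40), sel-1 (-0.30 to -0.15), pals-32 (0.17 to 0.36), rpl-29 (-0.30 to -0.16), mev-1 (0.23 to 0.49), his-42 (0.22 to 0.49) and cyb-2.1 (-0.36 to -0.18) moved by more than 1.5 times as well, and none of these changed sign. A list of transposon genes, sought by keyword, had 0 matches and was not tested.

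**Figure D2:**
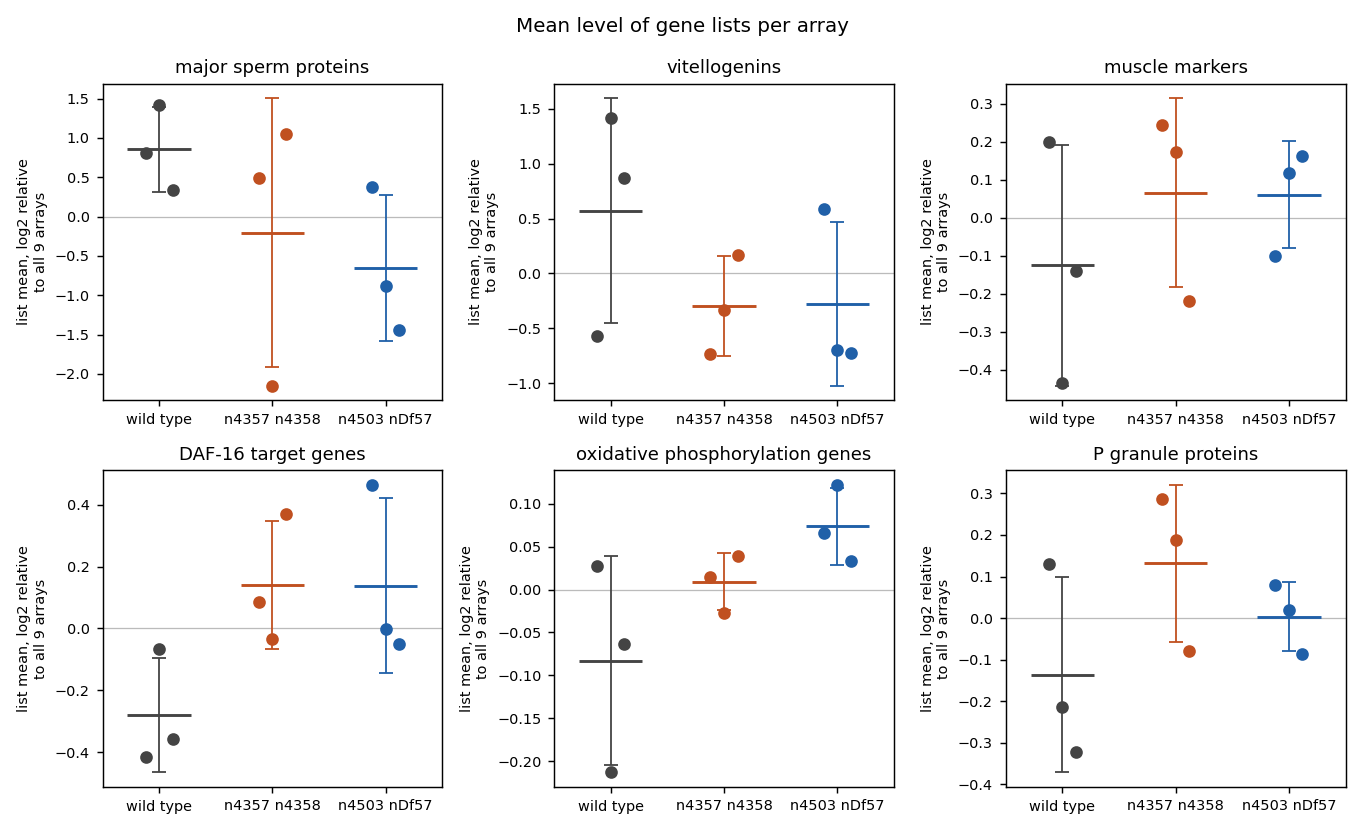
Mean level of 6 gene lists on each array, in log2 relative to all 9 arrays on the vertical axis, in the 3 groups on the horizontal axis; points are single arrays, horizontal lines group means and error bars SD (n = 3), and each panel has its own vertical scale. The major sperm proteins range from 0.33 to 1.42 in wild type, from -2.15 to 1.05 in n4357 n4358 and from -1.44 to 0.37 in n4503 nDf57; for the DAF-16 targets all mutant arrays lie above the wild-type arrays, the highest of which is at -0.07.

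In n4357 n4358 against wild type, bath-45 was 1.25 log2 higher (SE 0.16), with a limma adjusted p of 0.883 over all probe sets and 0.0193 adjusted over its list alone. The level of parn-1 was 0.58 higher (SE 0.14; 0.0307 adjusted over its list alone). P granule proteins were higher in 12 of 14 members with a median of 0.21 (camera adjusted p = 0.0104), led by glh-4 at 0.39 (SE 0.10). The same adjusted p of 0.0104 held for the muscle markers (median 0.13, tni-3 at 0.79, SE 0.20) and the oxidative phosphorylation genes (median 0.13, sdhb-1 of complex II at 0.34, SE 0.15). It held also for the DAF-16 targets (median 0.21, dod-3 at 1.53, SE 0.58) and the immune effectors (213 of 303 positive, median 0.09). Among the last, the antimicrobial peptide gene cnc-7 stood at 4.02 ± 0.13 log2 in wild type and 5.34 ± 0.37 in n4357 n4358 (SD, n = 3 each), a difference of 1.32 (SE 0.22). Cuticle collagens were higher in 107 of 147 members (median 0.12, camera adjusted p = 0.0438), although col-153 stood at -0.56 (SE 0.18). The major sperm proteins (median -1.03, adjusted p = 2.28e-06, msp-33 at -1.29 with SE 0.86) and vitellogenins (median -0.60, adjusted p = 0.0211, vit-4 at -1.64 with SE 0.76) were lower. So were the ribosomal proteins (median -0.02, adjusted p = 0.0420, rpl-41.1 at -0.25 with SE 0.13). These 9 calls were all lost with an estimated correlation, where the smallest adjusted p was 0.854. Without replicate 2 of this strain the major sperm protein median became -0.08. Without its replicate 3 the medians of the cuticle collagens and immune effectors became -0.09 and -0.01. The DAF-16 median became 0.03 without that array. Without wild-type replicate 2 the medians of the muscle markers, oxidative phosphorylation genes and vitellogenins became 0.0059, 0.02 and -0.10, and without wild-type replicate 1 that of the ribosomal proteins became 0.01. Each of these calls was lost. So was that of the P granule proteins without wild-type replicate 3, with a median of 0.13, and it passed in 6 of the 9 fits. Without shared probe sets the immune effectors alone passed (adjusted p = 0.0365). By limma 0 probe sets passed the threshold, and 899 had an unadjusted p under 0.05 against 1127.4 expected. With array weights 4 passed, 3 higher and 1 lower. In 982 and 1060 probe sets all arrays of the strain lay above or below wild type, where chance gives 1127.4 each way. Designs of 3 arrays against 3 allow no exact p under 0.1.

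In n4503 nDf57 against wild type, bath-45 was 1.75 log2 higher (SE 0.16), with a limma adjusted p of 0.0835 over all probe sets and 0.00146 adjusted over its list alone. The major sperm proteins were lower in all 23 members with a median of -1.56 (camera adjusted p = 5.18e-18), msp-32 standing at -1.15 (SE 0.47). The other sperm genes (41 of 57 negative, median -0.12, adjusted p = 9.08e-07) were lower too, with spe-10 at -0.35 (SE 0.11), as were the vitellogenins (median -0.41, adjusted p = 0.00202), with vit-4 at -1.58 (SE 0.76). Oxidative phosphorylation genes were higher in 31 of 33 members (median 0.16, adjusted p = 2.36e-08), with gas-1, a subunit of complex I, at 0.26 (SE 0.13). Muscle markers (30 of 32, median 0.16, adjusted p = 2.21e-04, tni-3 at 0.52 with SE 0.20) were higher. So were the DAF-16 targets (median 0.23, adjusted p = 0.00276, the glycolytic gene gpd-2 at 0.41 with SE 0.11) and histones (median 0.15, adjusted p = 0.00228, his-39 at 0.40 with SE 0.18). Ribosomal proteins (median -0.03, adjusted p = 0.0093, rpl-18 at -0.09 with SE 0.09) and proteasome subunits (median -0.04, adjusted p = 0.0275, rpn-12 at -0.19 with SE 0.13) were lower. None of these 9 calls held with an estimated correlation, where the smallest adjusted p was 0.804. With single arrays left out, the major sperm proteins, other sperm genes and oxidative phosphorylation genes passed the preset test in 9 of 9 fits. Their medians came as close to 0 as -1.14 and -0.04 without replicate 3 of this strain and 0.09 without wild-type replicate 2. The vitellogenins and muscle markers failed it without wild-type replicate 2, with medians of -0.21 and 0.07. The proteasome median became 0.0087 without replicate 3 of this strain, with its call lost. The calls of the DAF-16 targets, histones (median 0.06) and ribosomal proteins were lost without replicate 1 of this strain, although the DAF-16 median was 0.21 or more in every such fit. Those of the histones and of the ribosomal proteins were lost also without wild-type replicate 2 and wild-type replicate 1 in turn, the ribosomal median then being -0.0052. Without shared probe sets 3 of the 9 lists passed, the other sperm genes (median -0.07, adjusted p = 0.0338), DAF-16 targets (0.16, adjusted p = 0.0303) and oxidative phosphorylation genes (0.14, adjusted p = 1.27e-04), and the histone median turned to -0.07. Here too limma passed 0 probe sets; 637 had an unadjusted p under 0.05, and 906 and 577 had all arrays above or below wild type, against 1127.4 expected for each of these numbers. With array weights limma passed 37 probe sets, 32 higher and 5 lower.

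Genes of the propionate shunt, the route that breaks down propionate when vitamin B12 is scarce, were chosen after their values were seen. All 5 members examined were higher on every n4503 nDf57 array than on every wild-type array. The first enzyme's gene, acdh-1, stood at 7.18 ± 3.03 log2 in wild type, 7.77 ± 2.97 in n4357 n4358 and 11.36 ± 0.53 in n4503 nDf57 (SD, n = 3 each). Differences of n4503 nDf57 from wild type were 4.18 log2 for acdh-1 (SE 1.71), 1.66 for ech-6 (SE 0.36), 1.15 for hach-1 (SE 0.23), 2.27 for hphd-1 (SE 0.56) and 0.72 for alh-8 (SE 0.15). Over all probe sets the limma adjusted p was 1 for each of them, and with array weights 3 of the 5 passed the threshold. Without wild-type replicate 2 the acdh-1 difference fell to 2.47, and those of ech-6, hach-1, hphd-1 and alh-8 to 1.35, 1.01, 1.82 and 0.58. The lowest acdh-1 values were 3.77 on that array and 4.51 on n4357 n4358 replicate 2. On n4357 n4358 replicate 3 and n4503 nDf57 replicate 1, which lay apart like wild-type replicate 2, acdh-1 stood at 10.34 and 10.76. The 7 measured genes of the methionine cycle, which uses vitamin B12, had 4 positive and 3 negative differences with a median of 0.07, from -0.23 for sams-1 to 0.60 for mtrr-1.

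**Figure D3:**
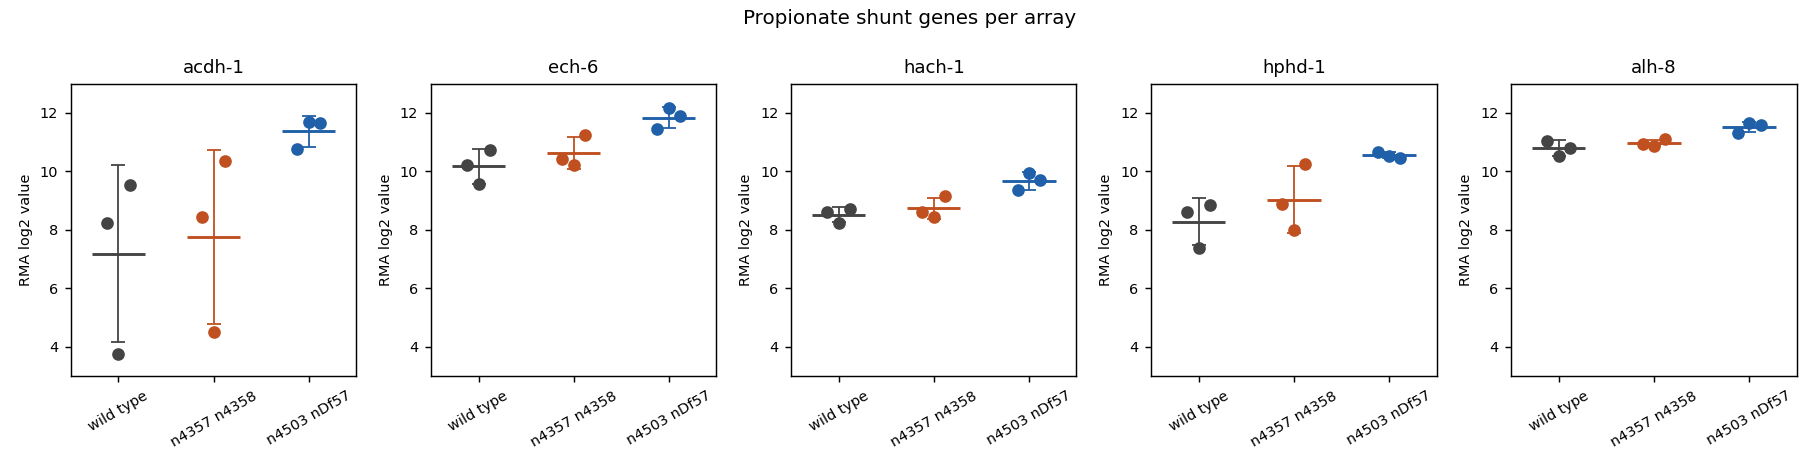
Array values of 5 propionate shunt genes, as RMA log2 values, in the 3 groups; points are single arrays, horizontal lines group means and error bars SD (n = 3). In each gene the 3 n4503 nDf57 arrays lie above the 3 wild-type arrays, and acdh-1 spans 3.77 to 9.54 within wild type alone.

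Both strains were compared for a shared response. bath-45 was higher in each, by 1.25 and 1.75 log2, and the major sperm proteins and vitellogenins had negative medians in each. By limma 0 probe sets passed the threshold the same way in both strains, from 899 and 637 with an unadjusted p under 0.05; with array weights 2 did, bath-45 and 1 probe set without a gene name. Differences from wild type correlated across probe sets, which are not independent replicates, at r = 0.597. In simulation, 200 pairs of unchanged groups, each pair sharing a control, gave a mean of 0.504 (95% of draws from -0.645 to 0.966). All simulated arrays, those of the control included, were redrawn with replacement from the pooled deviations inside the 3 groups. The covariance was 0.0352 against a simulated 0.0428, and 65.2% of probe sets had the same sign in both strains against a simulated 68.5%. Wild type has too few arrays to be divided between the strains, so part of any likeness may come from the shared control.

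The strains were also compared with each other, n4503 nDf57 minus n4357 n4358. The antimicrobial peptide gene cnc-7 had the smallest p, at 5.34 ± 0.37 log2 in n4357 n4358 and 4.02 ± 0.32 in n4503 nDf57 (SD, n = 3 each), a difference of -1.32 (SE 0.22; limma adjusted p = 0.977). Cuticle collagens were lower in n4503 nDf57 in 118 of 147 members (median -0.20, camera adjusted p = 6.45e-04), col-142 standing at -0.49 (SE 0.25), and immune effectors in 200 of 303 (median -0.11, adjusted p = 0.00304). Some reproductive lists were lower as well. They were the major sperm proteins (median -0.42, adjusted p = 0.0229, msp-32 at -0.73 with SE 0.47) and other sperm genes (median -0.13, adjusted p = 0.00669, spe-47 at -0.32 with SE 0.15). They also included the oocyte and eggshell genes (median -0.16, adjusted p = 0.0181, mex-6 at -0.24 with SE 0.11) and P granule proteins (median -0.11, adjusted p = 0.0437, glh-4 at -0.22 with SE 0.10). The vitellogenins (median 0.06) and meiotic chromosome proteins (median 0.0052) were not lower, with a camera adjusted p of 0.946 each. Heat shock genes (median -0.09, adjusted p = 0.0437, hsp-70 at -0.52 with SE 0.20) and proteasome subunits (median -0.08, adjusted p = 0.0224, rpn-10 at -0.28 with SE 0.14) followed. Higher in n4503 nDf57 were the RNA interference machinery (median 0.12, adjusted p = 0.0327, haf-6 at 0.28 with SE 0.15) and detoxification enzymes (median 0.09, adjusted p = 0.0181, ugt-50 at 0.66 with SE 0.20). The adjusted p was 0.998 for each of the 10 lists with an estimated correlation. Without replicate 3 of n4357 n4358 the medians of the cuticle collagens, immune effectors, major sperm proteins and RNA interference machinery turned to 0.05, 0.01, 0.22 and -0.04, and these calls were lost. Without the same array the other sperm genes lost their call with a median of -2.3e-04, and without replicate 1 of n4357 n4358 the oocyte and eggshell genes lost theirs with a median of -0.03. Of the 9 fits without single arrays, the P granule and heat shock lists passed in 4, the proteasome subunits in 5 and the detoxification enzymes in 6. In these fits the medians ran from -0.20 to -0.07 for P granule proteins and from -0.18 to -0.03 for heat shock genes. Those of the proteasome subunits and detoxification enzymes ran from -0.13 to -0.03 and from 0.05 to 0.10. Without shared probe sets 5 of the 10 lists passed, namely the RNA interference machinery, other sperm genes, cuticle collagens, heat shock genes and immune effectors. The level of bath-45 was 0.50 log2 higher in n4503 nDf57 (SE 0.16; limma adjusted p = 0.977). By limma 0 probe sets passed, 557 had an unadjusted p under 0.05, and 760 and 478 had the strains' arrays fully apart, against 1127.4 expected for each. With array weights 142 passed, 99 higher and 43 lower.

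Neighbours of the mutated genes were listed by gene order in the reference, assembly WBcel235, with 10 genes on each side. Around prg-1, 18 neighbours were measured; 0 had an unadjusted limma p under 0.05 in n4357 n4358 and 1 did in n4503 nDf57, mce-1 at 0.38. The lowest differences were -0.70 for rrf-1, an RNA-directed RNA polymerase of the soma, in n4357 n4358 and -0.37 for lrp-1 in n4503 nDf57. Around prg-2, 13 neighbours were measured and 0 had an unadjusted limma p under 0.05 in either strain, the lowest differences being -0.27 for best-9 and -0.35 for gtnt-2. No list of called genes existed, so their spread over chromosomes was not tested.

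Arrays varied more inside the groups than between them. The groups accounted for 20.7% of the total sum of squares, where 25% arises with no group effect, and correlations between arrays ran from 0.954 to 0.994 inside groups (9 pairs) and from 0.946 to 0.992 between groups (27 pairs). The first principal component held 49.8% of the variance, and wild-type replicate 2, n4357 n4358 replicate 3 and n4503 nDf57 replicate 1 lay on one side of it. The adult collagen gene col-19, chosen after its values were seen, stood at 7.29, 6.04 and 6.72 log2 on those arrays in turn, and at 3.53 and 4.80 on the other wild-type arrays, 3.98 and 3.64 on the other n4357 n4358 arrays and 3.42 and 3.49 on the other n4503 nDf57 arrays. Moulting genes, as a list mean relative to all 9 arrays, stood at -0.30, -0.67 and -0.65 on the same 3 arrays and between 0.13 and 0.40 on the others. All samples are labelled young adult, and whether all animals had passed the last moult was not tested. On the strongest component of variation inside the groups, the cuticle collagens, other sperm genes and immune effectors moved the opposite way to the moulting genes. Their median loadings on it were 0.89, 0.47 and 0.28. The difference between 3' and 5' probe sets, a sign of RNA integrity, differed between mutants and wild type by -0.11 for actin (exact permutation p = 0.226), -0.05 for catalase (p = 0.560, exact permutation), -0.15 for GAPDH (p = 0.0714, exact permutation) and -0.06 for ubiquitin (p = 0.298, exact permutation). The mean of the hybridisation controls was 9.97 ± 0.08 log2 in wild type, 9.51 ± 0.12 in n4357 n4358 and 9.88 ± 0.45 in n4503 nDf57 (SD, n = 3 each). The n4357 n4358 arrays lay below all wild-type arrays, with 9.64 as their highest value against 9.89 as the lowest in wild type.

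**Figure D4:**
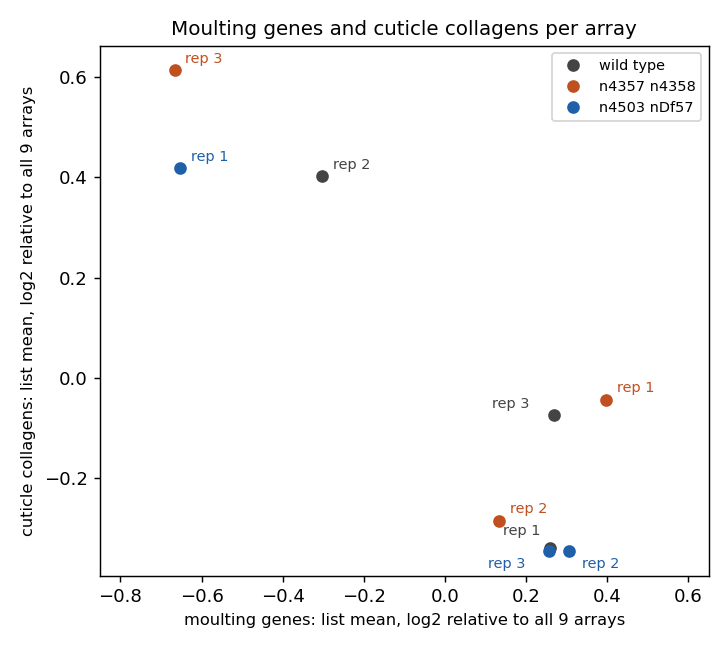
Mean of the cuticle collagen list (vertical axis) against the mean of the moulting gene list (horizontal axis) on each array, both in log2 relative to all 9 arrays, with 1 point per array coloured by group. Wild-type replicate 2, n4357 n4358 replicate 3 and n4503 nDf57 replicate 1 lie at moulting values of -0.30, -0.67 and -0.65 and collagen values of 0.40, 0.61 and 0.42.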

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

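All tests in this part were chosen after the result was seen. Data outside the comparisons held 1 signal. Control probe sets that are named for worm genes or by a number alone, and which entered no test of expression, were higher on all 6 mutant arrays than on all 3 wild-type arrays in 7 of 27 cases, against 0.321 expected by chance, and lower on all in 0. For GAPDH, a glycolytic enzyme, the mean of both mutants exceeded wild type by 0.29 log2 in the 3' probe set, by 0.44 in the 5' probe set and by 0.36 in the middle one. The others belong to a pair of controls with no gene name given, with differences of 0.33 (3') and 0.44 (5') for one and 0.33 (3') and 0.39 (5') for the other. All 7 stayed positive under cyclic loess and under centring on ribosomal and proteasome genes, and all arrays stayed apart in 7 and 6 of them. Probe sets of 1 transcript are not independent of each other, so the number expected by chance understates how often several move together.

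bath-45 was higher in both mutants, by 1.5 log2 in the mean, and is the piRNA target named in advance that differed. With the moulting genes as a covariate a difference of 1.53 (SE 0.10) was left. The moulting genes differed by only -0.11 log2 between mutants and wild type, so this adjustment could hardly change the difference. It concerns timing around the moult alone, and timing of the germline or of adult age was not tested. With the hybridisation controls as a covariate 1.47 (SE 0.18) was left. That adjustment rests largely on the spread inside n4503 nDf57 (SD 0.45), so it decides little. The controls were lower on all 3 n4357 n4358 arrays than on all wild-type arrays. Lower hybridisation as the whole source is argued against by n4503 nDf57 replicates 1 and 3. Their controls stood at 10.1 and 10.17 log2, against at most 10.05 in wild type. There bath-45 stood at 6.10 and 6.25, against at most 4.62 in wild type. The prg-1 and prg-2 mutations, by which the labels set the groups apart, stay open as a hypothesis and may account for the bath-45 difference, as may a background variant common to both strains, which was not tested.

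The 5 propionate shunt genes were higher in n4503 nDf57 than in wild type, by a mean of 2.0 log2. That value was again 2.0 (SE 0.74) with the moulting genes as a covariate. The moulting list means were 0.07 in wild type and -0.03 in n4503 nDf57, too alike for this adjustment to change the value much. Developmental timing was therefore not decided by it. The deviations of these genes from their group means rose and fell together at a mean pairwise correlation of 0.804, at percentile 99.98 of random sets of 5 genes, so a candidate explanation is a culture condition, such as the vitamin B12 content of the food, that varied between cultures inside groups too. Genes of 1 regulated pathway are expected to move together under any input, so this does not separate culture from genotype, and an effect of the n4503 nDf57 background stays open and untested.

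Wild-type replicate 2, n4357 n4358 replicate 3 and n4503 nDf57 replicate 1 lay apart from the other 6 arrays. Loss of RNA integrity as the whole source is argued against, since in 0 of 4 control transcripts did the 3' minus 5' difference place these arrays on one side of the others. This rule asks for full separation and would miss a partial difference. Other aspects of RNA quality were not tested. The mean of the poly-A and yeast controls was 3.38, 3.77 and 3.48 log2 on these arrays in turn. On the others it lay between 3.31 and 3.38, so a technical source in labelling or background stays open. Background or compression that acts by level stays open for part of the pattern, since all 3 arrays had a smaller distance between the quartiles than each of the other 6, whose lower quartiles reached at most 3.70 and upper quartiles at least 6.45 log2, but for the cuticle collagens it is argued against by a median loading at percentile 100 of 10000 random lists of the same level. Moulting genes lay at percentile 0, with a median loading of -1.21 against -0.16 for random lists, which is consistent with animals harvested at different times around the last moult. No biological explanation by genotype was tested, because each group holds 1 of these arrays.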

How the results depend on the processing

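The alternatives with a covariate or only 6 arrays, and the splits described under other observations, were chosen after seeing the data; the rest were not. Of the 813 values of 39 single gene results tested over all probe sets under 25 alternatives, 793 kept their direction and their side of the threshold, 11 passed it anew, all of them bath-45, and 9 reversed. A kept direction does not mean a kept size. Over 21 alternatives the mean differences of mex-6, rpn-12 and sel-1, among others, came as close to 0 as 0.04, -0.03 and -0.04. Array weights changed the numbers of called probe sets most, from 0 to 4 in n4357 n4358, 37 in n4503 nDf57, 2 in the mean of both, 142 between the strains and 2 the same way in both. The weighted mean of each mutant strain rests mostly on its replicate 2. All calls with array weights, for single genes too, therefore say little about the other arrays of these strains. In n4503 nDf57 and in the mean of both, 1 probe set, bath-45, passed under cyclic loess, with the within-group component as a covariate and with the moulting genes as a covariate. The within-group component was taken from these same data after the group means were removed. As a covariate it cannot shift a group difference and lowers the remaining spread by construction, so a pass with it adds no support. For bath-45 in the mean, the adjusted p over all probe sets ran from 0.00147 to 1 over 21 alternatives, and over its list alone from 2.58e-05 to 0.0258 over 22. For parn-1 the adjusted p over its list alone ran from 0.00401 to 0.152 and was below the threshold in 13 of 22. Leaving out each array in turn gave 0 to 2 called probe sets in n4503 nDf57 (2 without its replicate 1, both of them the lower probe sets of cpt-4, a gene named after its values were seen, and 1, bath-45, without n4357 n4358 replicate 3), 0 to 1 in the mean and 0 in the others, and 7 to 11 gene lists. The 9 gene lists became 2 without shared probe sets and 0 with an estimated correlation. For xol-1 the difference reversed in n4357 n4358 under cyclic loess (-0.040) and centring (-0.00090), and in n4503 nDf57 with only 6 arrays (-0.0081). Leaving out single arrays spanned -0.059 to 0.066 for xol-1 in n4357 n4358, -0.0022 to 0.088 in n4503 nDf57 and -0.0025 to 0.063 in the mean, and -0.052 to 1.19 for prg-1 in n4357 n4358. The cause was not tested. The replicate numbers did not pair the arrays, since 3 of 9 same-numbered pairs correlated above 0.1 and 0 of 9 arrays matched best with their own number; with a replicate block limma called 0 probe sets in every comparison, 10 gene lists passed, prg-1 and prg-2 stood at 0.75 and -0.35, and the call of parn-1 over its list alone ended (0.0623). Levels near the floor, as for xol-1, limit what signal over background can show.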

Other observations

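All tests in this part were chosen after the result was seen, as were the genes named in it. Several probe sets lay on one side of wild type on all 6 mutant arrays without passing the test over all probe sets. A probe set named for the nuclear hormone receptor gene nhr-88, of a kind that can detect several related genes, stood at 5.12 ± 0.27 log2 in wild type, 6.61 ± 0.55 in n4357 n4358 and 6.62 ± 0.51 in n4503 nDf57 (SD, n = 3 each). The other 3 probe sets of nhr-88 had mean differences of 0.27, 0.08 and -0.04, so the difference is not that of the gene as a whole. The alcohol dehydrogenase gene adh-1 stood at 8.21 ± 0.58, 9.32 ± 0.14 and 9.76 ± 0.46 in the same order, and the cytochrome c gene cyc-2.2 at 5.79 ± 0.33, 4.30 ± 0.88 and 3.96 ± 0.31. The C-type lectin gene clec-47 set n4503 nDf57 apart, at 7.42 ± 0.93 log2 against 5.0 ± 0.18 in wild type and 5.18 ± 0.46 in n4357 n4358. The lysozyme gene lys-4 was at 10.54 ± 0.82 in wild type, 8.55 ± 0.38 in n4357 n4358 and 9.77 ± 0.04 in n4503 nDf57. Their limma adjusted p-values against wild type were 0.883 or more in every comparison. With array weights adh-1 (1.86, adjusted p = 0.0343) and the first nhr-88 probe set (1.78, adjusted p = 0.0331) passed the threshold of limma in n4503 nDf57 against wild type. Between the strains lys-4 (1.54, adjusted p = 0.0445) and clec-47 (1.83, adjusted p = 0.0452) passed it with array weights in limma. Without wild-type replicate 2 the lys-4 difference of n4503 nDf57 from wild type shrank from -0.77 to -0.30.

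From the ends of the strongest component of variation inside the groups 2 genes were taken. The collagen gene col-120 ran from 5.06 to 10.15 log2 in wild type, from 4.76 to 9.98 in n4357 n4358 and from 4.92 to 10.26 in n4503 nDf57. The lipocalin-related gene lpr-3 of the precuticle ran the other way, at 8.09 on the wild-type array where col-120 stood at 10.15, and at 11.11 where col-120 stood at 5.06. Over all genes this component held 59.8% of the variance inside the groups.

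Other splits of the arrays into groups of the same sizes were counted for each comparison. Where the real number of called probe sets is 0, every split reaches it, so these counts say nothing about chance. That holds for the mean of both mutants (84 of 84 splits, highest other 2037), for probe sets called the same way in both strains (100 of 100 drawn splits, highest other 714) and for n4357 n4358, n4503 nDf57 and the strains against each other (10 of 10 splits, highest other 1 in each). Splits with as many as 2037 calls point to a structure of the arrays. For gene lists in the mean of both mutants 51 of 84 splits gave at least the real 9, up to 20, and with array weights 33 of 84 gave at least the real 2 probe sets, up to 10790, so chance is not excluded for either. The other comparisons have 10 splits each, too few for a share under 0.05. Gene lists reached the real 9 in 8 of 10 splits for n4357 n4358 (highest other 20), the real 9 in 5 of 10 for n4503 nDf57 (highest other 13) and the real 10 in 6 of 10 between the strains (highest other 15). With array weights the real 4 probe sets in n4357 n4358 were reached in 3 of 10 splits (highest other 543), the real 37 in n4503 nDf57 in 2 of 10 (highest other 686) and the real 142 between the strains in 7 of 10 (highest other 8730).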
